A study of Homo sapiens with 8 samples.

How the data were processed

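Small RNA libraries from HEK293 cells, 4 with 100 nM ASO and 4 without, were compared after 48 h. Total RNA was extracted with a Qiagen miRNeasy kit and libraries were made with a NEB small RNA kit, per the labels' protocols. Adapter ligation and PCR favour some small RNA sequences over others, so counts compare a microRNA between libraries better than they compare different microRNAs. Base calls were converted with bcl2fastq 2.20, reads were trimmed with Trimmomatic 0.30, GRCh38 was the genome build and edgeR 3.4.6 was used, per the submitters' processing notes. The aligner, the counter and the source of the microRNA annotation are not given in the sources used here. Libraries were assigned to groups by their titles.

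The authors deposited a single table with a count per entry and library, which are whole numbers and not normalized. It also holds 8 columns that the authors headed TPM, which proved on testing to be CPM: each equals the count scaled to its library's total, with no division by length, and differs from a CPM computed here by at most 0.223 CPM. The deposited table further gives a length of 18 to 25 for each entry, which was used only to describe the sequences. The tests ran on the counts. Of the 2867 entries, 7 were at 0 in every library, and 1203 of the 1964 predicted ones were above 0 in a single library. In 142 entries the count was 0 in some libraries and at least 100 in others. Some entries carry identical counts (miR-92a-3p and miR-92a-2-3p, for example), so they are not independent. Of 17 hairpins with both arms listed, 3 had equal counts of at least 20 for both arms in at least 1 library. An entry may therefore not always separate the arms. Counts of replicate pairs differed by more than sampling noise (chi-square per degree of freedom of 135 to 801 over entries with at least 20 counts in a pair), so no pair looked like a repeat deposit of 1 library. This does not show that the libraries came from separate cultures, since differences in preparation also exceed sampling noise.

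The test had been fixed before the data were examined, as limma on log2 FPKM values unless counts were present, in which case edgeR's quasi-likelihood test was to be used. The table held counts, so edgeR was used, and the filter and pseudocounts that had been set in FPKM were carried over to counts and CPM, in the same numbers. Entries above 0 in at least 4 of the 8 libraries with a mean count of at least 10 were tested, which left 539 known and 206 predicted microRNAs. Counts were scaled with TMM (factors 0.964 to 1.02), a trended dispersion was fitted and p-values were two-sided with Benjamini-Hochberg adjustment at a threshold of 0.05. Standard errors of log2 fold changes were the size of the change divided by the square root of the quasi-likelihood F. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels give no batch, and shared library numbers are not stated to pair libraries, so no block was used.

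Single values were compared with exact two-sided permutation tests, where the 70 arrangements of 4 and 4 libraries allow a smallest p of 0.0286. Lists were tested with camera (correlation preset at 0.01, and estimated) and fry where at least 3 members were tested, with Benjamini-Hochberg adjustment over the 18 lists. The 21 lists were the target, the miR-17-92, miR-106b-25 and miR-106a-363 clusters, the let-7, miR-15/16, and miR-29 and miR-30 families, the group of miR-10, miR-99, miR-100 and miR-125, the group of miR-181, miR-221 and miR-222, the stem cell, 14q32 and 19q13 clusters, Drosha-independent, p53-induced, immune-induced, and hypoxia and stress microRNAs, and markers of blood cells, mesenchyme and endothelium, epithelium, liver and muscle, and neural cells. A list took either arm of each of its hairpins, so it can hold an arm with another seed than its family. It also took entries named without a copy number, so miR-92a-3p can be counted beside miR-92a-1-3p or miR-92a-2-3p. Named microRNAs followed a rule set with the tests. It took the miR-31 entries, up to 10 in each direction past the threshold with non-overlapping groups, where fewer than 5 passed the smallest p up to 5 as values that missed, the 10 most abundant, and from each list the most abundant member and the member with the smallest p. Further members of lists (miR-15a-5p, miR-210-3p, miR-23a-3p, miR-1-3p, miR-181a-5p, miR-155-5p, miR-132-3p and miR-34a-5p) were named as examples after their values were seen.

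Total counts per library ran from 8168828 to 11677123, so 1 count is 0.0856 to 0.122 CPM, and the limit of 3 counts that a count of 0 allows is 0.257 to 0.367 CPM. Wilson 95% intervals and these limits cover counting error only, since PCR copies are not independent molecules. On simulated counts with 200 of the 745 entries changed, the test recovered 6% of 1.5-fold, 26.9% of 2-fold and 62.1% of 4-fold changes. Among the 539 known microRNAs alone it recovered 23.9%, 64.2% and 84.8% of changes of these sizes, and among the 550 entries above 0 in all 8 libraries 67.2%, 91% and 100%. Each set had 200 changed entries, so the share changed differed between sets and was far above the share called in the data. Benjamini-Hochberg adjustment is less strict when more entries change, so recovery is likely lower where few do, and the sets are not directly comparable. Counts were also drawn independently for each entry, without differences shared by a whole library.

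Hairpin positions, host genes and sequences came from GENCODE version 29 on GRCh38, where 811 of the 903 known entries matched a single microRNA gene by name. Alternatives fixed with the test were other pseudocounts in limma, other filters, median-ratio and quantile scaling, no variance trend, sample quality weights, a replicate block (fitted in edgeR, like the main test) and leaving out each library. Chosen after seeing the data were the fits on known microRNAs and on entries above 0 in all 8 libraries, identical entries counted once, DESeq2, limma on log2(CPM + 1), robust shrinkage, and leaving out ASO library 2 with control library 4. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.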

Results

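Small RNA was sequenced from HEK293 cells, an established human embryonic kidney cell line, after transfection of an antisense oligonucleotide (ASO), a short synthetic nucleic acid that base-pairs with a chosen RNA. The library names give miR-31 as the target, and the series title describes ASOs that hold precursor microRNAs in a fixed shape. The stated question was whether the ASO changed small RNAs other than its target. There were 4 libraries from cells given 100 nM ASO and 4 from cells given none, all harvested after 48 h. No group was given an unrelated ASO, so a difference between groups cannot be told apart from an effect of any ASO. The titles of the controls do not say whether they were mock-transfected. Total counts were 10139807, 11677123, 11136043 and 10082129 in ASO libraries 1 to 4, and 10496804, 9611877, 8168828 and 11228954 in control libraries 1 to 4. The table held 2867 entries, of which 903 were known microRNAs carrying 99.1% of all counts and 1964 were predicted microRNAs. Levels below are TMM-normalized CPM (counts scaled to the library total), given as mean ± SD over n = 4 libraries per group.

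The mean level of miR-31-5p, the mature strand cut from the 5′ arm of the target hairpin, was not lower in the ASO libraries. It was 837 ± 166 CPM with ASO and 736 ± 305 CPM in controls. The hairpin gene MIR31 lies at chromosome 9, 21512115 to 21512185 on the minus strand (GRCh38), in an intron of the long noncoding RNA gene MIR31HG, and miR-31-5p was the 1 miR-31 entry in the table. Whether this entry holds the 5′ arm alone was not checked, since entries may not always separate the arms. In ASO libraries 1 to 4 the level was 776, 916, 1018 and 637 CPM, from 7563, 10843, 11322 and 6556 counts. In control libraries 1 to 4 it was 350, 657, 880 and 1056 CPM, from 3525, 6143, 7303 and 11969 counts. With the lowest count the Wilson 95% interval ran from 325 to 347 CPM before TMM scaling, so the spread between libraries was far wider than the counting error. The fitted log2 fold change was 0.19 (SE 0.33, 95% interval −0.57 to 0.95, adjusted p = 0.851), which is a fold of 1.14 with an interval of 0.671 to 1.93. An exact permutation test of the difference in mean log2 level, 0.28, gave p = 0.571. Of the 745 entries tested, 468 had a change at least as large in size as that of miR-31-5p and 511 had a smaller p. Without control library 1, which held the least miR-31-5p, the log2 fold change turned to −0.04, and it was 0.08 without ASO library 3, 0.29 without ASO library 4 and 0.41 without control library 4. Since the target did not separate the groups, it gave no check of the labels, and every direction below rests on them.

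**Figure D1:**
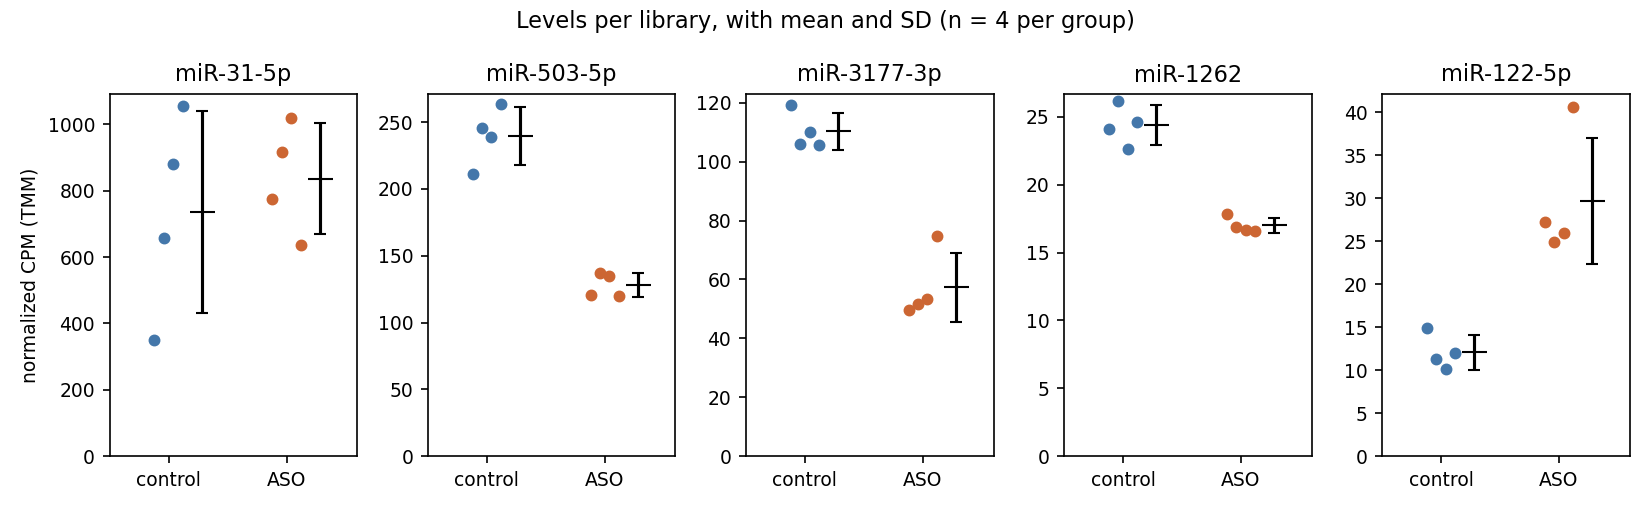
Normalized CPM (vertical axis, starting at 0) of the target and 4 further microRNAs in each library, control and ASO side by side, with the group mean and SD (n = 4). The groups overlap for miR-31-5p, while for miR-503-5p the ASO libraries lie between 120 and 137 CPM, below all 4 control libraries.

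Among other small RNAs, miR-503-5p, a member of the miR-15/16 family that restrains cell-cycle genes, fell from 240 ± 21.7 CPM in controls to 128 ± 9.07 CPM with ASO. This was 1.87-fold lower (95% interval 1.62 to 2.16), with a log2 fold change of −0.91 (SE 0.09, adjusted p = 0.00854), and all 4 ASO libraries lay below all 4 controls. MIR503 lies on chromosome X, 134546328 to 134546398 on the minus strand, in an intron of MIR503HG. It was the 1 entry of 745 that passed the threshold in edgeR's quasi-likelihood test, and 0 entries rose. At an unadjusted p under 0.05 there were 78 entries, where 37.25 would be expected by chance, and DESeq2 called 9 entries higher and 14 lower. In 62 entries (8.32%) the 4 ASO libraries did not overlap the 4 controls, where chance gives 2.857% of independent entries, but regroupings of the same 8 libraries gave up to 93 such entries and 3 of the 35 gave at least 62.

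A further 3 microRNAs just missed the threshold over all 745 entries, each with an adjusted p of 0.0516, and each had ASO and control libraries that did not overlap. miR-3177-3p averaged 57.3 ± 11.7 CPM with ASO and 110 ± 6.35 CPM in controls (log2 fold change −0.94, SE 0.14). Its gene MIR3177 lies on chromosome 16, 1734985 to 1735066 on the plus strand, in an intron of MAPK8IP3. miR-1262 averaged 17.0 ± 0.583 CPM with ASO and 24.4 ± 1.46 CPM in controls (−0.52, SE 0.08), and MIR1262 lies on chromosome 1, 68183518 to 68183610 on the minus strand, in an intron of WLS, which encodes a carrier of Wnt proteins. miR-122-5p, the dominant microRNA of liver, averaged 29.7 ± 7.34 CPM with ASO and 12.1 ± 2.02 CPM in controls (1.30, SE 0.20, 2.46-fold). MIR122 lies on chromosome 18, 58451074 to 58451158 on the plus strand, in an exon of MIR122HG.

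When the 539 tested known microRNAs were fitted without the predicted ones, an alternative chosen after seeing the data, edgeR called 1 higher and 3 lower. miR-122-5p rose (log2 fold change 1.27, adjusted p = 0.0272), and miR-503-5p (−0.93, adjusted p = 0.00169), miR-3177-3p (−0.97, adjusted p = 0.0240) and miR-1262 (−0.54, adjusted p = 0.0240) fell. With a mean count of at least 100, an alternative fixed beforehand, the same 4 passed among 358 entries together with miR-222-3p, which targets the cell-cycle inhibitor CDKN1B (−0.22, adjusted p = 0.0494). miR-222-3p averaged 7857 ± 244 CPM with ASO and 9082 ± 103 CPM in controls, and over all 745 entries it missed the threshold (−0.21, SE 0.04, adjusted p = 0.134). The call of miR-503-5p was lost without control library 2 (adjusted p = 0.0602; log2 fold change −0.95 to −0.86 over the libraries left out), with the filter removed (adjusted p = 0.113), without both ASO library 2 and control library 4 (adjusted p = 0.0577) and with the library number as a replicate block (−0.90, adjusted p = 0.241). Leaving out 1 library moved the count between 0 (without control library 2) and 5 (without control library 4), with 2 without ASO library 1, ASO library 4, control library 1 or control library 3, and moved the count among known microRNAs between 1 and 3.

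**Figure D2:**
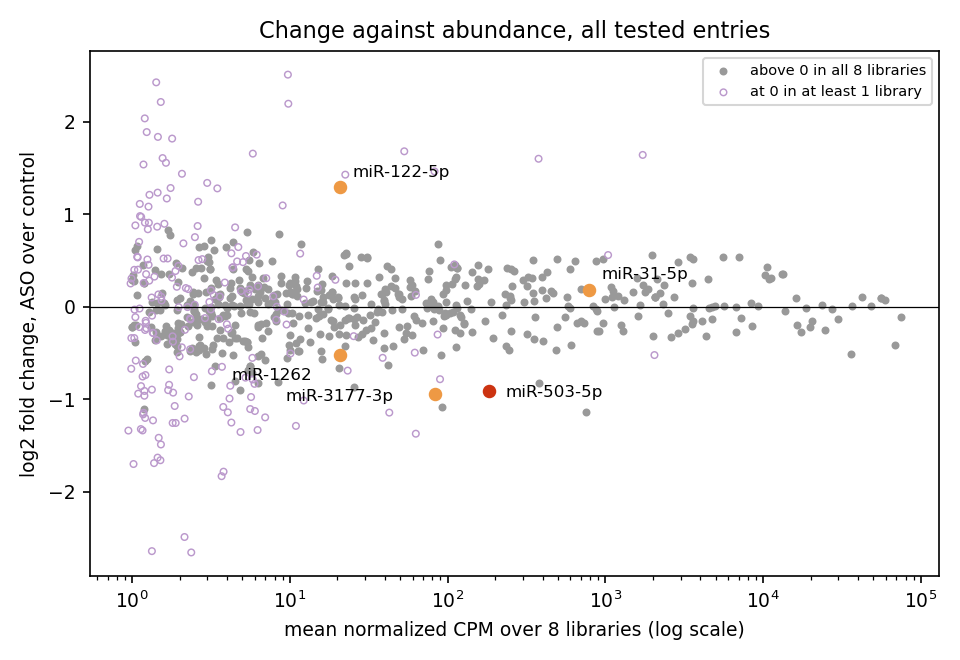
Fitted log2 fold change, ASO over control (vertical axis), against mean normalized CPM over the 8 libraries (horizontal log axis) for the 745 tested entries, with the microRNAs named in the text marked. The widest scatter lies among entries at 0 in at least 1 library, and the most abundant microRNAs lie near 0.

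Other entries with small unadjusted p did not pass the threshold in the main test. Among those with a higher mean with ASO were miR-329-3p of the imprinted cluster at 14q32 (log2 fold change 0.68, adjusted p = 0.3003), miR-146a-5p, which is induced by NF-kB (0.41, adjusted p = 0.402), miR-3065-5p (0.54, adjusted p = 0.402) and miR-576-5p (0.31, adjusted p = 0.402). miR-184 averaged 18.1 ± 2.12 CPM with ASO and 33.1 ± 8.99 CPM in controls (−0.87, SE 0.20, adjusted p = 0.349).

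The 10 most abundant entries did not pass the threshold either. miR-21-5p, widely raised in tumours, averaged 71616 ± 4918 CPM with ASO and 77127 ± 7859 CPM in controls (log2 fold change −0.11, adjusted p = 0.627). miR-7-5p averaged 58399 ± 7272 and 77970 ± 18156 CPM (−0.42, adjusted p = 0.445), and miR-148a-3p 29879 ± 4220 and 42565 ± 15165 CPM (−0.51, adjusted p = 0.445). In control library 1 alone these stood at 101787 CPM for miR-7-5p and 63687 CPM for miR-148a-3p, against 70030 ± 10784 and 35524 ± 6893 CPM in the other 3 controls, and without it the log2 fold changes were −0.25 and −0.23. let-7a-5p, of the family that represses RAS and HMGA2, averaged 48144 ± 1912 CPM with ASO and 47874 ± 1084 CPM in controls (0.01, SE 0.04, adjusted p = 0.972), and let-7f-5p also had a log2 fold change of 0.01. The remaining 5 were the miR-92a entries miR-92a-1-3p (0.07), miR-92a-2-3p and miR-92a-3p (0.09 for both, with identical counts), miR-26a-5p (0.11) and miR-10a-5p (−0.13). The let-7a-5p and let-7f-5p directions flipped with median-ratio scaling and in the fit on known microRNAs (−0.02 for both), and those of miR-21-5p and miR-10a-5p with quantile normalization. Without control library 1 miR-10a-5p turned to 0.014, miR-21-5p was −0.032 (−0.064 without ASO library 3) and the miR-92a entries were 0.029 to 0.043, and miR-92a-1-3p was 0.045 without ASO library 1.

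Of the 21 lists fixed beforehand, 18 had at least 3 tested members, and camera called 0 of them with a preset correlation of 0.01. At an unadjusted p under 0.05 camera gave 4 lists, fry called 1 list for a change on balance in a single direction and 1 for changes in either direction. Camera's smallest adjusted p with an estimated correlation was 0.538.

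The hypoxia and stress list, which holds miR-210, the best-known hypoxia-induced microRNA, and the miR-23a/27a/24 cluster, had the smallest camera p. All 8 tested members had a fold above 1 and none passed the threshold (median log2 fold change 0.19, camera adjusted p = 0.106, adjusted p = 0.538 with an estimated correlation), and 0 passed when adjusted over the list alone. miR-210-3p had a log2 fold change of 0.32, miR-27a-3p 0.22, miR-23a-3p 0.49 and miR-24-1-3p 0.10. MIR24-1 lies on chromosome 9, apart from MIR27A on chromosome 19. With quantile normalization 4 of the 8 had a fold above 1, and miR-24-1-3p turned to −0.05. On leaving out 1 library miR-27a-3p was 0.13 (without ASO library 3) and miR-24-1-3p 0.067 (without ASO library 2).

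In the list of the miR-15/16 family, whose 5p arms target cyclins and BCL2, miR-503-5p fell while the other 7 tested members, of which miR-16-3p and miR-424-3p are opposite arms without the family's seed, had a fold above 1 (5 of them with quantile normalization) and did not pass the threshold. miR-16-5p averaged 1029 ± 119 CPM with ASO and 727 ± 194 CPM in controls (log2 fold change 0.50, adjusted p = 0.445), and miR-15a-5p had a log2 fold change of 0.54. The list's median was 0.22 (camera adjusted p = 0.330, or 0.651 with an estimated correlation), and fry's test for changes in either direction gave an adjusted p of 0.000252. Adjusted over the list alone, 1 member fell and 0 rose.

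The liver and muscle markers were the list called by fry for a single direction (adjusted p = 0.0129). All 3 tested members had a fold above 1 (median 0.19, camera adjusted p = 0.122, or 0.538 with an estimated correlation), and adjusted over the list alone 1 passed, miR-122-5p. The muscle microRNAs miR-499a-5p (0.11, or 0.038 without control library 2 and 0.18 without control library 3) and miR-1-3p (0.19) did not pass. The stem cell clusters, which hold the pluripotency-associated miR-302 microRNAs, had 2 of 5 tested members with a fold above 1 and a median of −0.33 (camera adjusted p = 0.215). Adjusted over the list alone 2 members fell, miR-302b-3p (29.3 CPM with ASO and 37.6 CPM in controls, log2 fold change −0.36) and miR-302a-5p (33.3 and 45.3 CPM, −0.44), though 0 passed over all entries. In the list of miR-181, miR-221 and miR-222, microRNAs that regulate lymphocyte and vascular cell growth, 5 of 6 members had a fold above 1 (median 0.28, camera adjusted p = 0.179). Adjusted over that list alone miR-222-3p fell, while miR-221-3p, made from the same locus, had a log2 fold change of 0.30 (0.19 without control library 1) and miR-181a-5p 0.26.

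In the main test no member of the lists that follow passed the threshold, over all entries or adjusted over the list alone. In the 14q32 cluster, an imprinted locus active in embryo and placenta, 23 of 30 members had a fold above 1 (median 0.14, camera adjusted p = 0.147). Among the clusters that promote proliferation downstream of MYC, the fold was above 1 in 4 of 5 members of miR-17-92 (median 0.09, camera adjusted p = 0.353), 6 of 7 of miR-106a-363 (0.44, camera adjusted p = 0.179) and 1 of 3 of miR-106b-25 (−0.02, camera adjusted p = 0.816, where camera's direction was up). In these counts miR-92a-3p can stand beside miR-92a-1-3p or miR-92a-2-3p, so not every member is a separate microRNA. The lowest member of miR-17-92 was at −1.37, and 4 of its 5 tested members were above 0 in all 8 libraries. miR-18a-5p of that cluster was at 0 in ASO libraries 1, 2 and 4 and in control library 1. miR-17-5p had a log2 fold change of 0.49, miR-93-5p 0.54, miR-363-3p −0.16 and miR-25-3p −0.02, the last turning to 0.06 with quantile normalization. In control library 1, miR-17-5p stood at 1413 CPM and miR-93-5p at 3483 CPM, against 2715 ± 442 and 6465 ± 1167 CPM in the other 3 controls, and without it miR-17-5p had a log2 fold change of 0.31. The fold was above 1 in 7 of 9 members of the let-7 family (4 of 9 with median-ratio scaling, median 0.01, camera adjusted p = 0.816), 7 of 9 of the miR-29 and miR-30 families (0.28, camera adjusted p = 0.179) and 4 of 8 of the group of miR-10, miR-99, miR-100 and miR-125 (−0.06, camera adjusted p = 0.658). The lowest p in these 3 lists belonged to let-7i-5p (−0.27, or −0.14 without control library 1), miR-29a-3p (0.30) and miR-100-5p (−0.30).

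Lists of cell responses showed no call in the main test. DESeq2, chosen after seeing the data, called miR-146a-5p and miR-155-5p of the immune-induced list. Of the immune-induced microRNAs, which respond to NF-kB, interferon or transfected nucleic acid, 5 of 9 had a fold above 1 (median 0.15, camera adjusted p = 0.391), with miR-155-5p at 0.24 and miR-132-3p at 0.15. Of the p53-induced microRNAs 5 of 9 had a fold above 1 (0.02, camera adjusted p = 0.569), with miR-34a-5p at 0.33, miR-107 at 0.51 and miR-192-5p at −0.27. miR-192-5p stood at 1731 CPM in control library 1, against 1300 ± 176 CPM in the other 3 controls, and without that library its log2 fold change was −0.13. Of the microRNAs made without the nuclear enzyme Drosha, 5 of 6 had a fold above 1 (0.15, camera adjusted p = 0.330), with miR-320a-3p at 0.11 (0.16 without ASO library 1, 0.071 without ASO library 2, 0.066 without ASO library 4) and miR-484 at 0.30 (0.19 without control library 1). Markers of other cell types passed in neither direction outside the liver and muscle list. The fold was above 1 in 4 of 5 epithelial markers (0.16, camera adjusted p = 0.330), with miR-200b-3p at −0.11 (−0.045 without control library 1) and miR-429 at 0.22, in 4 of 6 mesenchymal and endothelial markers (0.30, camera adjusted p = 0.330), with miR-126-3p at −0.02 and miR-199b-3p at 0.44, and in 2 of 7 neural markers (−0.19, camera adjusted p = 0.330), with miR-128-1-3p at −0.22 and miR-129-5p at −0.46. Without control library 1 the values were −0.10 for miR-128-1-3p, −0.23 for miR-129-5p and 0.26 for miR-199b-3p, which was 0.78 without control library 4. The blood cell markers had 1 tested member, miR-486-5p (−0.02), and the 19q13 cluster, active in placenta, had 2, miR-516b-5p (−0.57, or −0.30 without control library 2) and miR-1323 (0.61), so neither list was tested as a group. With an estimated correlation the adjusted p of every list tested was between 0.538 and 0.865.

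The libraries did not differ detectably between groups in complexity. Entries above 0 numbered 1191 ± 84.9 with ASO and 1168 ± 68.1 in controls, a difference of 23.25 (exact permutation test, two-sided, p = 0.686), which turned to −18.8 without ASO library 1. The 10 most abundant entries took 49.3% ± 1.18 of counts with ASO and 51.4% ± 1.65 in controls, a difference of −2.08 points (exact permutation p = 0.143). The 50 most abundant took 89.3% ± 0.306 with ASO and 90.1% ± 0.719 in controls, a difference of −0.83 points (exact permutation p = 0.0571). Predicted microRNAs took 1.01% ± 0.0881 and 0.771% ± 0.214 of counts (exact permutation p = 0.114). The first principal component of the libraries, with 41.1% of the variance, set control library 1 (12.6) apart from the other 7 libraries (−6.94 to 1.53). Without that library the log2 fold changes of 23 of the 50 named microRNAs moved by over 1.5 times or turned sign, against 6 to 9 of the 50 without each other library. The second, with 26.7%, set ASO library 2 (−8.06) and control library 4 (−6.29) apart from the rest.

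**Figure D3:**
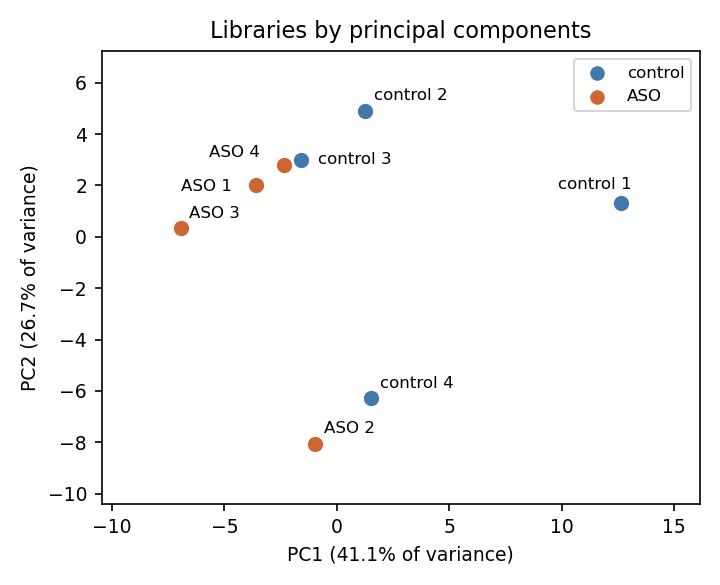
The 8 libraries on the first and second principal components (axes, with 41.1% and 26.7% of the variance), ASO and control in different colours and each point labelled with its library. Control library 1 lies alone on the first component, and ASO library 2 and control library 4 lie together at the low end of the second.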

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

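Among the tests in this part, those of control library 1 for abundant features and for a wrong label, both tests of entries at 0, the tests of a single deciding library and of the MIR503 neighbours, and the splits for non-overlapping groups among all tested entries were chosen only after the results were seen, as were the fits on known microRNAs and on entries above 0 in all 8 libraries.

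A single library stood far from the other 3 of its group in 4 of 108 group comparisons, where chance gives about 1 in 20, or 5.4. miR-122-5p was at 40.6 CPM in ASO library 4 and at 24.9 to 27.3 CPM in the other ASO libraries. miR-3177-3p was at 74.6 CPM in ASO library 4 and at 49.5 to 53.5 CPM in the other ASO libraries. miR-381-3p of the 14q32 cluster was at 85.2 CPM in ASO library 1 and at 71.6 to 72.5 CPM in the other ASO libraries. ASO library 1 had 1317 entries above 0, and the other ASO libraries had 1140 to 1164.

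For the fall of miR-503-5p with ASO, the unadjusted p stayed at 8.09e-05 or lower without each library in turn, so no single library made the difference, although without control library 2 the adjusted p was 0.0602 and the call was lost. The other tested microRNAs of the MIR424-MIR503 locus (miR-424-3p, miR-450a-5p, miR-450b-5p and miR-542-3p) had a median log2 fold change of 0.037, from −0.14 to 0.15. This argues against a shared fall of the mature microRNAs of the locus. The primary transcript was not measured, so these levels cannot decide whether it fell. An effect of the ASO on miR-503-5p itself stays open as an untested hypothesis, and without an unrelated ASO it cannot be told apart from an effect of any ASO. Of the 35 splits of the 8 libraries into 4 and 4, 14 called at least as many entries as the real 1, with a highest other count of 3, so chance cannot be excluded for that count. Among known microRNAs 1 of the 35 splits, the real one, reached its 4 calls (highest other 2), and among entries above 0 in all 8 libraries, a filter that drops any entry that fell to 0, again 1 of 35 reached 4 (highest other 0). That share is the smallest that 35 splits can give, and both sets were chosen after the count of 1 was seen. It therefore does not exclude chance for those 2 counts. Among known microRNAs the count was 1 without ASO library 1, ASO library 3 or control library 2 and 0 with the replicate block (70 at an unadjusted p under 0.05).

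Control library 1 stood apart on the first component and held the least miR-31-5p. Its log2 miR-31-5p lay at −1.28 relative to the mean of the other controls (SD 0.35), and at −1.23 with the 50 most abundant features left out, so a few abundant features taking the counts do not account for it. Hairpin GC content and mature length explained 0.928% of the variance of its deviations over 422 features and left miR-31-5p at −1.19 (−1.25 before). miR-503-5p was also called without control library 1 (edgeR adjusted p = 0.00577). It stood at 211 CPM in that library, outside the 120 to 137 CPM of the ASO libraries. This was nearer the 239 to 264 CPM of the other controls, but it was known when the test was chosen. A predicted entry also called without control library 1 was at 6.75 CPM there, 2.87 to 5.41 CPM in the ASO libraries and 0 in the other controls. These 2 entries point opposite ways and cannot decide whether an ASO library was labelled as control. Among entries above 0 in all 8 libraries, which leave out the predicted entry, the 3 called without control library 1 were all on the control side there. A difference between cultures or library preparations, which the labels do not give, stays open.

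Entries at 0 in some libraries and at 100 counts or more in others numbered 142 (31 known), of which 47 were tested. Sampling can account for 0.0% of their 726 zeros. In 28 of the 142 (19.7%) another entry repeats the counts and keeps them where the first is at 0, and in 0 of them did the zeros follow the groups. These values are consistent with entries being listed library by library in the upstream processing, and they remain a limit on any entry with a 0, such as miR-103a-3p at 131770 and 166935 counts in ASO libraries 1 and 3 and 0 elsewhere. No biological explanation was tested for them.

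Among all 745 tested entries 62 had groups that did not overlap, as many were found in 3 of the 35 splits and the highest other count was 93. Among entries above 0 in all 8 libraries, 53 of 550 (9.64%) had groups that did not overlap, where chance gives 2.857%. Again 3 of the 35 splits had as many, so chance cannot be excluded for either count. The highest other counts, 93 and 84, both came from ASO libraries 1, 2 and 3 with control library 4 against the rest, which points to a structure of the libraries that their groups do not follow. For the lists, camera called 0 in the real split, so that 35 of 35 splits had to give at least as many and nothing follows about chance. The highest other was 1. In the real split camera gave 4 lists at an unadjusted p under 0.05, and fry called 1 list for a single direction and 1 for either direction.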

How the results depend on the processing

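Chosen only after the results were seen were DESeq2, limma on log2(CPM + 1), robust shrinkage, identical entries counted once, the fits without ASO library 2 and control library 4, and every fit on known microRNAs alone or on entries above 0 in all 8 libraries.

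The level of miR-31-5p stayed short of the threshold in every setting run, and its log2 fold change was positive in all of them except those without control library 1. The count of changed entries, 1 in the main test, was 4 with log2(CPM + 0.1), 2 with log2(CPM + 10), 3 with log2(CPM + 1), 5 with a mean count of at least 100, 3 with quantile normalization, 4 with sample quality weights, with identical entries counted once and with robust shrinkage, and 23 with DESeq2, which gave no adjusted p to 323 entries. Without the filter edgeR called 0 of 2860 entries, 160 of them at an unadjusted p under 0.05, which follows in part from the larger number of tests. The count was 4 among known microRNAs and 3 among these in 3 against 3 libraries. Among entries above 0 in all 8 libraries it was 4, and 3 in 3 against 3 libraries. The settings on all 8 libraries that called exactly 4, except the replicate block, called the same 4 microRNAs, miR-503-5p, miR-3177-3p, miR-1262 and miR-122-5p, and DESeq2 called these too. Further DESeq2 calls included miR-146a-5p, miR-155-5p, miR-329-3p, miR-29a-3p, miR-16-3p, miR-181a-5p, miR-222-3p, miR-302b-3p, miR-3065-5p and miR-184. With median-ratio scaling, and without the variance trend, the call was miR-503-5p alone. With 3 against 3 libraries over all entries 1 predicted entry was called and miR-503-5p was not (adjusted p = 0.0577). The replicate block, which takes library numbers as pairs, gave 0 calls in edgeR over all entries (65 at an unadjusted p under 0.05) and 0 among known microRNAs (70 at an unadjusted p under 0.05), but 4 among entries above 0 in all 8 libraries, 3 of them of the same 4. Same-number correlations of the deviations from group means were 0.03, −0.52, 0.42 and −0.37 for numbers 1 to 4. ASO library 3 was the 1 ASO library that correlated best with its own number. These values gave little sign of pairing by number. They cannot exclude it, since single libraries stood far apart and the labels do not say. The adjusted p of miR-503-5p over leave-one-out fits of the main test ran from 0.00577 to 0.0602.

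The number of entries with a change at least as large as that of miR-31-5p, 468 in the main test, was 138 with log2(CPM + 10), 2453 without the filter, 198 with a mean count of at least 100, 293 among entries above 0 in all 8 libraries (188 with 3 against 3 libraries, 202 with the replicate block), and 246 (replicate block) and 212 (3 against 3) among known microRNAs, part of which follows from the number tested. Camera called 1 list with log2(CPM + 0.1), log2(CPM + 10), log2(CPM + 1) and sample quality weights, each time hypoxia and stress (adjusted p = 0.0350, 0.00721, 0.0393 and 0.00998, or 0.518, 0.498, 0.521 and 0.570 with an estimated correlation). It called 1 list, liver and muscle markers, among entries above 0 in all 8 libraries (adjusted p = 0.0479, or 0.406 with an estimated correlation) and there with the replicate block (adjusted p = 0.0312, or 0.687).

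Leaving out each library in turn, over all 3 sets of entries, gave counts from 0 to 6, a rank of miR-31-5p from 146 to 682, 0 to 2 lists called (14q32 cluster, hypoxia and stress, or liver and muscle markers, all among entries above 0 in all 8 libraries, with adjusted p of 0.254 to 0.592 with an estimated correlation) and a miR-31-5p change from −0.059 to 0.42. The difference in entries above 0 ran from −18.8 to 54.4. Changes near 0, none of them called, turned sign on leaving out libraries for let-7a-5p (−0.018 to 0.019), let-7f-5p (−0.025 to 0.022), miR-10a-5p (−0.19 to 0.014), miR-381-3p (−0.063 to 0.16), miR-486-5p (−0.065 to 0.032), miR-126-3p (−0.050 to 0.034), miR-25-3p (−0.060 to 0.019) and miR-30a-5p (−0.059 to 0.029). They also turned without the filter for miR-486-5p (0.0013) and miR-30a-5p (0.010), with median-ratio scaling for let-7a-5p (−0.0026) and let-7f-5p (−0.0031), and with quantile normalization for miR-21-5p (0.084), miR-10a-5p (0.039), miR-381-3p (−0.0034), miR-24-1-3p (−0.047), miR-25-3p (0.061) and miR-30a-5p (0.068). Where no cause is given above, the cause was not tested. Depth limits entries near 10 counts, where 1 count is up to 0.122 CPM.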

Other observations

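Of the tests in this part, the 6-base windows, GGGAAC and the repeats of the correlation on other sets were chosen only after the results were seen.

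Short stretches shared with the target hairpin were noticed in miR-503-5p and miR-3177-3p after these were known to be lower. The ASO sequence is not given in the labels, so the MIR31 hairpin itself was searched, without gaps, with 1 for a match and −1 for a mismatch. The sequences compared with it came from the hairpin of each microRNA. A match is therefore one between hairpins. It can lie outside the mature strand that was counted, and this was not checked for any microRNA below. The best match of miR-3177-3p was ACTGGGGAC against ACTGGGAAC in the hairpin (score 7, reached by 39.6% of 482 known microRNAs), that of miR-1262 was CTGGGAAC (8, reached by 15.6%) and that of miR-503-5p was GGGAAC (6, the median, reached by 75.3%). miR-122-5p, which was higher with ASO, scored 9 (reached by 6.02%). Against the middle of the hairpin these scores were reached by 17.2% (miR-3177-3p), 7.47% (miR-1262), 44.6% (miR-503-5p) and 2.49% (miR-122-5p), so the least common match of the 4 belonged to the microRNA that was higher. A hypothesis is that an ASO against MIR31 may also lower microRNAs that resemble the hairpin. Across 482 known microRNAs with a hairpin, which are not independent replicates, the score against the whole MIR31 hairpin had a Spearman rho of −0.105 with the log2 fold change (Pearson −0.0817, permutation p = 0.0212, adjusted over 7 tests p = 0.0247). Against the middle of the hairpin (positions 21 to 50 of 71) rho was −0.147 (Pearson −0.109, permutation p = 0.00115, adjusted p = 0.0031). Without the 4 microRNAs called among entries above 0 in all 8 libraries it was −0.143 (permutation p = 0.00177, adjusted p = 0.0031), and without control library 1 it was −0.137 (permutation p = 0.00258, adjusted p = 0.00361). After removing hairpin GC and lengths it was −0.145 (permutation p = 0.00138, adjusted p = 0.0031), and in the fit on entries above 0 in all 8 libraries −0.196 (permutation p = 7e-05, adjusted p = 0.00049). When the middle of each of 476 other hairpins was used in place of that of MIR31, 9 (1.89%) gave a rho as low. The rho of these other hairpins ranged from −0.206 to 0.190, with a median of −0.032. This argues against base composition shared by all hairpins as the whole account. The permutation p-values shuffled microRNAs and not libraries, so they treat microRNAs as independent and are likely too small. Leaving out the 4 called microRNAs, 3 had GGGAAC in the hairpin sequence searched. Their median log2 fold change was lower by a difference of −0.17 (permutation p = 0.429, adjusted p = 0.429), and they are too few to decide. Of 41 windows of 6 bases along the hairpin, CTGGGA ranked 4th from the lowest, with a median of −0.15 over 14 features and 0.05 over the others, and TGCCAA was lowest (−0.25 over 8). The highest was ACCTGC, at positions 41 to 46 in the middle stretch (0.34 over 10), so the windows point both ways. These values are compatible with a weak relation to the MIR31 sequence, too small to account for any single microRNA. miR-122-5p went the other way, and its match, like the others, may lie outside its mature strand. The tests come from the same 8 libraries as the idea.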
